A study of Mus musculus with 3 samples.

How the data were processed

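RNA from 3 pools of wild-type mouse neural retina at postnatal day 14 was hybridised to Affymetrix U74Av2 arrays, 1 array per pool, per the labels' titles and descriptions. The labels place all 3 samples in one group, and nothing in them pairs the samples or gives a batch. Every sample is described as a pool of 3 to 4 animals. That the pools hold different mice is assumed here and not stated in the labels. Whether littermates were split between pools is not given in the sources used here, so the spread between pools may include shared litters.

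The authors deposited 1 signal intensity per probe set and array, on a linear scale, for 12488 probe sets of which 66 are controls. The software and its settings are not given in the sources used here. The values themselves show a per-array scaling: after 2% of the probe sets was trimmed at each end, the mean signal was 500.26, 500.26 and 500.28 on the arrays of pools 1, 2 and 3, with a spread of 0.0057% between arrays. Detection calls and probe-level values were not used here. If the scaling was a single factor per array, which the values do not show, a few very bright transcripts could change the scale little. A difference in the dim range, such as the larger share of signals under 16 in pool 3, was left in the values. The deposited scaling was kept, as fixed before the data were examined for trimmed means within 5% of each other.

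Probe sets were named from the platform annotation given for the array, with 10833 carrying 1 gene symbol, 396 several and 1193 non-control probe sets not listed in it. Only probe sets with 1 symbol were named; of these, 10817 had their Entrez identifier in the mouse RefSeq gene table (assembly GRCm38.p6), which was used for symbols and synonyms only. These probe sets stood for 8251 genes, 2073 of them with several. No genome was used, and no coordinates are given. A gene's level was the mean of its probe sets on the log2 scale; among the 111 genes chosen by the naming rules from lists, 32 had several probe sets and for 16 these differed by over 2 log2 units, so their mean level is uncertain.

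Signals were analysed as log2(signal + 16). The offset damps the noise of dim probe sets and understates their differences. The between-pool spread was the SD over the 3 arrays. Excess variance was tested with limma 3.58.1 in R 4.3.3: an intercept-only fit with eBayes and a trended prior gave each probe set's residual variance (2 degrees of freedom) and its prior variance (8.29 degrees of freedom), and their ratio was referred to an F distribution, upper tail, with Benjamini-Hochberg adjustment over the 6211 probe sets whose mean was above the median, and a threshold of 0.05. On simulated data with these probe sets' means and prior variances, no change gave 0 false calls, and the prior's degrees of freedom were refitted as 7.21. With 20 probe sets raised on one array, 0% of those raised 4-fold, 40% of those raised 8-fold and 100% of those raised 16-fold or 32-fold were called. With 200 raised, none was called at any fold, since so many raised probe sets widened the fitted prior. The test is therefore blind to widespread differences.

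The 26 gene lists (369 genes, 278 measured, none in more than one list) were written before the data were examined, and so were the tests, thresholds and naming rules. They cover retinal cell types, other tissues that dissection could bring, and general pathways. A list's median level was placed among 10000 random lists of the same number of genes, and called bright within the top 0.1% and dim within the bottom 0.1%. For shifts, the median over the list of one array minus the mean of the other 2 was placed among 10000 random lists matched on mean level in 20 bins. Lists with fewer than 5 measured genes, here the sex-linked list, had no percentile. Random lists treat genes as independent, so the percentiles of co-regulated lists are too extreme. The floor of an array was the 95th percentile of its 15 Bacillus subtilis control probe sets, and a gene was above it when at least 1 of its probe sets exceeded it on all 3 arrays.

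The text names the first 4 measured members of each list in the written order, all measured sex-linked genes, the 3 members of each shifted list with the largest difference (Mip and Gja3 without a difference, as they lie below the floor in some pools), and the 15 variable probe sets with the largest variance ratio. The second Cryge probe set, which was the 16th, was chosen after its values were seen. So were the further probe sets of Cryab, Crybb2, Crygb, Crygd, Cryge and Tmem129, and the single ones of Glul, Hk2 and Junb. Tyr and the further genes named in the closing section were also chosen after their values were seen. No sample comparison reached beyond replicates of one group, so no test between groups was made. Alternatives were an offset of 0 with values under 1 set to 1, an offset of 64, median centring, quantile normalization, each pool left out, other filters on dim probe sets, untrended and robust priors, the brightest probe set per gene, other floors and limits of 0.5% in place of 0.1%. Level percentiles in each pool alone, and list shifts with every signal under 168.32, the highest floor of the 3 arrays, raised to it, were added after seeing the data. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the lists and matplotlib 3.10.9 for the figures.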

Results

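Gene expression was measured in the neural retina of wild-type mice at postnatal day 14, an age at which the mouse eye opens and photoreceptors are still lengthening their outer segments. The mice carried a mixed 129/SvEv and C57BL/6 background and were wild-type littermates of animals lacking Rp1, a photoreceptor axoneme protein; the mutant retinas were not analysed here. Each of the 3 samples was RNA from a pool of 3 to 4 mice, collected between 1 and 2 pm and hybridised to 1 Affymetrix U74Av2 array. The 3 pools form a single group, so the data answer which transcripts the retina of this age holds and how far replicate pools differ, and they allow no contrast between conditions. Pool numbers follow the order of deposition and carry no other meaning.

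The arrays shared a common scale, with 2%-trimmed mean signals of 500.26 in pools 1 and 2 and 500.28 in pool 3. Median signals were 238 in pool 1, 242 in pool 2 and 207 in pool 3, and signals under 16 made up 4.49%, 5.49% and 9.80% of probe sets. Across the 12422 probe sets that are not controls, Pearson's r between arrays on the log2(signal + 16) scale was 0.916 for pools 1 and 2, 0.926 for pools 1 and 3 and 0.927 for pools 2 and 3; probe sets are not independent replicates. The SD between the 3 pools had a median of 0.27 on the log2 scale among the 6211 probe sets with a mean above the median, and 0.63 among the 3106 probe sets of lowest mean signal against 0.24 among the 3106 of highest. The 3′ control probe set of Gapdh, a glycolytic enzyme, stood at -0.25 ± 0.16 (SD, n = 3) relative to the 5′ one on the log2 scale, and that of beta-actin at 0.53 ± 0.21 (SD, n = 3). Bacterial and phage spike-in probe sets had a median difference from the other arrays of 0.65 in pool 1, 0.19 in pool 2 and -0.77 in pool 3. The number of arrays limits the precision of every value below.

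Genes of rods, outer segments, energy metabolism, Müller glia, synapses and lens gave brighter signals than random sets of genes did. Of 25 gene lists fixed before the data were examined, 7 had a median level within the top 0.1% of 10000 random lists of the same number of genes. These were rod phototransduction, the outer segment with its cilium and matrix, oxidative phosphorylation, glycolysis, Müller glia, synapse and ribbon, and lens. No list lay within the bottom 0.1%. Of the 278 list genes measured, 189 lay above the control probe floor on all 3 arrays, set by 15 probe sets of bacterial genes at signals of 168, 121 and 104 in pools 1, 2 and 3; among all 8251 named genes the share was 62.7%. The percentiles describe these arrays, and probe affinity also enters each level, so levels of different genes were not ranked against each other.

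**Figure D1:**
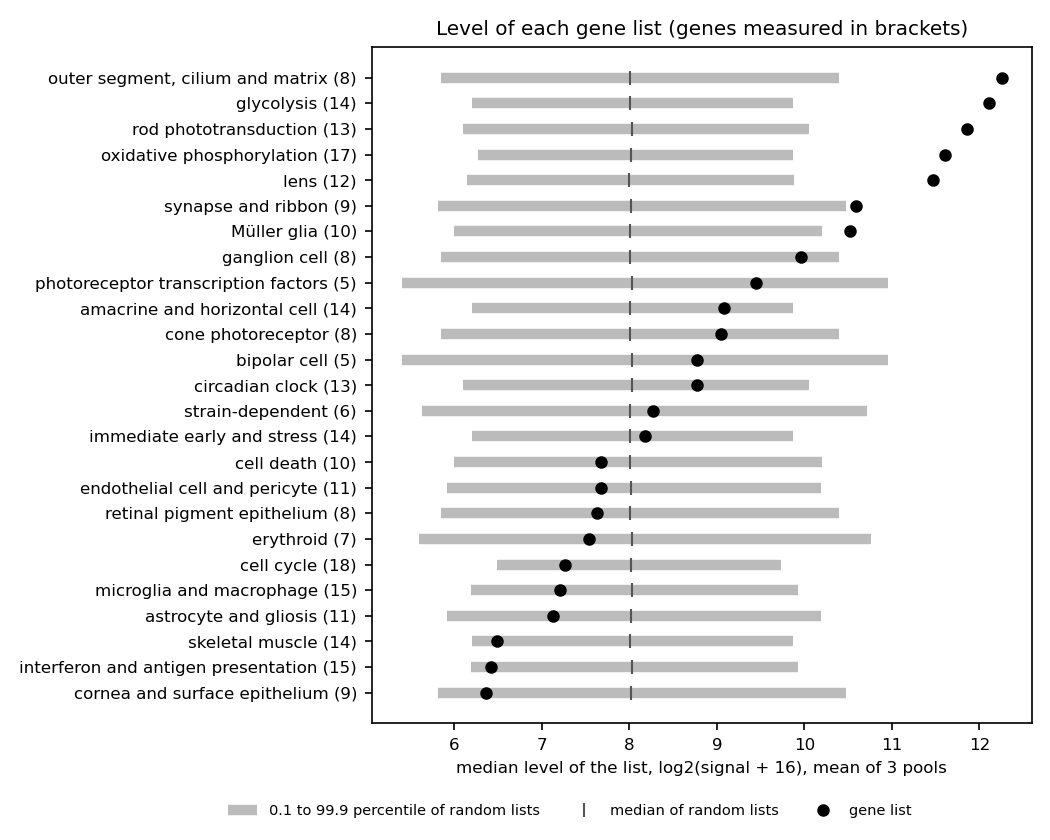
Median level of each of the 25 gene lists on the log2(signal + 16) scale, averaged over the 3 pools (points, with the number of genes measured in brackets), beside the range of 10000 random lists of the same size without the top and bottom 0.1% (bars) and their median (ticks). The 7 lists to the right of their bars include rod phototransduction at 11.85 and the outer segment list at 12.26.

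Rod phototransduction genes had a median level of 11.85, with 12 of 13 measured members above the floor. Gnat1, the rod transducin alpha subunit, measured 14.95 ± 0.44 (log2 signal, mean ± SD, n = 3 here and throughout). Where a gene had several probe sets the value is that of their mean, and its SD can hide probe sets that moved apart. The rod phosphodiesterase subunits measured 12.36 ± 0.20 for Pde6b, 14.78 ± 0.18 for Pde6g and 11.25 ± 0.18 for Pde6a. The outer segment list had a median of 12.26, with 8 of 8 measured members above the floor. In it the disc rim protein Prph2 measured 11.22 ± 1.07, its partner Rom1 11.77 ± 0.13, the retinoid transporter Abca4 12.75 ± 0.31 and Prom1 12.93 ± 0.09. The photoreceptor transcription factors lay at the 92.0th percentile, with all 5 measured members above the floor. Crx measured 12.72 ± 0.15, the rod determinant Nrl 9.45 ± 0.29, Neurod1 11.92 ± 0.35 and Esrrb 8.10 ± 0.34. Cone genes lay at the 90.2th percentile, with 5 of 8 above the floor. The cone opsins measured 10.12 ± 0.61 for Opn1mw and 11.23 ± 0.70 for Opn1sw, the cone transducin Gnat2 10.73 ± 0.26, and the cone channel Cnga3, not above the floor on every array, 6.53 ± 0.70.

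Genes of ganglion, amacrine, horizontal and bipolar cells lay mostly above the floor. All 8 measured ganglion cell genes lay above the floor, with the list at the 99.4th percentile. The neurofilaments Nefl, Nefm and Nefh measured 10.26 ± 0.23, 8.83 ± 0.37 and 10.03 ± 0.23, and Thy1 10.99 ± 0.33. Of the amacrine and horizontal cell genes 12 of 14 lay above the floor. Gad1, which makes GABA, measured 11.86 ± 0.06, Gad2 6.10 ± 0.18 without passing the floor, the glycine transporter Slc6a9 11.19 ± 0.27 and calbindin Calb1 9.81 ± 0.26. All 5 measured bipolar cell genes lay above the floor, at the 75.9th percentile. Pcp2 measured 9.90 ± 0.19, Prkca 8.78 ± 0.09, the channel Trpm1 8.20 ± 0.10 and Isl1 9.95 ± 0.43. The synapse and ribbon list had a median of 10.59, with 8 of 9 members above the floor. Its members included Pclo at 9.44 ± 0.12, the ribbon component Ctbp2 at 11.61 ± 0.12, the calcium sensor Syt1 at 11.91 ± 0.31 and Bsn at 6.52 ± 1.03, not above the floor on every array. The synapse and ribbon list, at percentile 99.945, fell short of the top 0.1% without pool 1, at 99.865, and with the brightest probe set standing for each gene, at 99.89.

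Müller glial genes had a median of 10.52, with 9 of 10 above the floor. Glutamine synthetase Glul measured 10.16 ± 0.13, the retinaldehyde-binding protein Rlbp1 12.13 ± 0.12, Apoe 9.07 ± 0.67 over a pair of probe sets that differ by 7.49 log2 units, and the water channel Aqp4 9.21 ± 0.25. The Glul probe sets moved in opposite directions, with signals of 1379.5, 2595.7 and 1995.5 in pools 1, 2 and 3 against 1035.6, 389.3 and 702.7. Glycolytic genes had a median of 12.11, with all 14 above the floor, including Hk1 at 11.98 ± 0.32, Ldha at 13.97 ± 0.20, Pkm at 13.48 ± 0.21 and Hk2 at 7.80 ± 0.27. The brighter Hk2 probe set had signals of 475.9, 1153.9 and 1428 in pools 1, 2 and 3. The other, at 80.3, 46.9 and 8, lay below the floor. Oxidative phosphorylation genes had a median of 11.60, with 15 of 17 above the floor, including Atp5a1 at 13.07 ± 0.12, Cycs at 8.88 ± 0.10 and Cox4i1 at 8.21 ± 0.25; Cox5a, at 6.39 ± 0.67, was not above it. Circadian clock genes lay at the 86.7th percentile, with 12 of 13 above the floor. Arntl measured 10.60 ± 0.15, Per1 8.61 ± 0.58, Per3 8.77 ± 0.33 and Per2, not above the floor on every array, 6.56 ± 0.51.

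Cell cycle, microglial, gliosis, muscle, surface epithelial and interferon genes gave dimmer signals than most random lists. Cell cycle genes lay at the 9.59th percentile, with 8 of 18 above the floor; Mki67 measured 5.91 ± 0.17, Top2a 5.16 ± 0.61, Cdk1 6.77 ± 0.96 and Ccna2, the one of these above the floor, 9.38 ± 0.33. Microglia and macrophage genes lay at the 9.87th percentile, with 7 of 15 above the floor, including Csf1r at 8.12 ± 0.24 and Cx3cr1 at 8.50 ± 0.61 but not Aif1 at 5.69 ± 0.92 or Itgam at 5.95 ± 0.80. Astrocyte and gliosis genes lay at the 11.2th percentile with 5 of 11 above the floor, among them Gfap at 7.03 ± 0.25, Pax2 at 7.41 ± 0.39 and Lcn2 at 7.41 ± 0.66, with S100b at 7.12 ± 0.42 not among them. Skeletal muscle genes lay at the 0.66th percentile with 4 of 14 above the floor, and Acta1 measured 7.60 ± 0.29, Ckm 6.62 ± 0.54, Myh4 6.70 ± 0.93 and Myh1 5.33 ± 1.31. Corneal and surface epithelial genes lay at the 1.42th percentile with 3 of 9 above the floor, and Krt12 measured 7.96 ± 0.26, Krt5 7.21 ± 0.70, Krt14 5.32 ± 0.37 and Krt15 5.10 ± 0.50. Interferon and antigen presentation genes lay at the 0.51th percentile with 6 of 15 above the floor, and B2m measured 8.05 ± 0.12, H2-D1 7.96 ± 0.13, H2-K1 7.80 ± 0.29 and Cd74 7.95 ± 0.18. The probe sets of H2-D1, H2-K1, Myh4 and Mki67 differed by up to 4.29, 2.71, 2.63 and 2.29 log2 units.

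The remaining lists lay between these. Endothelial and pericyte genes were at the 32.6th percentile, with 6 of 11 above the floor, and Pecam1 measured 8.32 ± 0.42, Cldn5 9.61 ± 0.23, Cdh5 7.51 ± 0.28 and Tek 6.55 ± 0.24. Cell death genes were at the 33.3th percentile with 6 of 10 above the floor, and Bcl2 measured 7.53 ± 0.18, Apaf1 8.24 ± 0.11, Bcl2l1 7.83 ± 0.23 and Casp9 8.35 ± 0.34. Immediate early and stress genes were at the 60.1th percentile with 11 of 14 above the floor, and Fos measured 6.91 ± 0.39, Jun 7.88 ± 0.25, Egr1 7.81 ± 0.46 and Junb 7.52 ± 0.04. Junb was not above the floor on every array. Its probe sets moved in opposite directions, with signals of 223.4, 58.3 and 116 in pools 1, 2 and 3 against 135.5, 425.9 and 229.3. The probe sets of Fos and of Egr1 differed by 3.41 and 3.69 log2 units, and those of Bcl2 and of Bcl2l1 by 4.12 and 4.82. Genes often reported to depend on mouse strain were at the 61.1th percentile with 4 of 6 above the floor, and Glo1 measured 12.56 ± 0.11, Ide 7.97 ± 0.21, Nnt 7.0 ± 0.49 and Pttg1 6.77 ± 0.97. The Ide probe sets differed by up to 2.40 log2 units.

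Lens transcripts set the pools apart. Set against the mean of the other pools, the lens list differed by -2.64 log2 units in pool 1, 1.97 in pool 2 and 0.73 in pool 3 (median over 12 genes; percentiles 0, 100 and 100 among 10000 random lists matched on level). The signal of Crygs, a structural crystallin, was 2436 in pool 1, 62142 in pool 2 and 31496 in pool 3. That of Cryaa, the alpha-crystallin chaperone, was 6826, 64668 and 39281, and that of the lens fibre channel Mip 102.6, below the floor of 168, 1756 and 936. In pool 2 Crygs and the beaded filament protein Bfsp1 differed from the mean of the other pools by 2.82 and 2.27 log2 units. Crygc and Crygs differed by 1.38 and 1.35 in pool 3 and by -3.61 and -4.17 in pool 1. No difference is given for Mip, below the floor in pool 1, or for the fibre connexin Gja3, below it in pools 1 and 3. The lens list also lay among the bright lists in pool 1 alone, at the 99.96th percentile with a median of 10.05, and 10 of its 12 measured genes were above the floor in all 3 pools. Without pool 1, the difference of pool 3 was -0.86 (pool 3 minus pool 2), and without pool 2 it was 2.26, so its direction in this list depends on which pools it is set against. A single array was set against 2 others, so these are differences between these libraries and carry no p-value.

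Pigment epithelium genes were the other list that stood apart. Their level was at the 31.4th percentile, with 2 of 8 genes above the floor in all pools. Set against the mean of the other pools, the list differed by 0.56 log2 units in pool 3 (99.92th percentile, 8 genes), 0.18 in pool 2 and -0.58 in pool 1 (0.16th). Ttr, the thyroxine carrier made by pigmented epithelia of the eye, had signals of 108, 400.3 and 751.8 in pools 1, 2 and 3. The melanosome genes Pmel and Dct had signals of 362.5, 808.1 and 1041, and of 619, 815.5 and 1088. Rgr measured 7.34 ± 0.38 and Rdh5 7.92 ± 0.39, while the 4 probe sets of Tyrp1, with a mean of 5.93 ± 0.15, differed in direction and Tyr had signals of 124.1, 123.8 and 79.8. Ttr, Rgr and Rdh5 were below the floor in pool 1. The list lay inside the percentiles under quantile normalization (99.85), with the brightest probe set per gene (99.88) and without pool 1 (97.87).

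**Figure D2:**
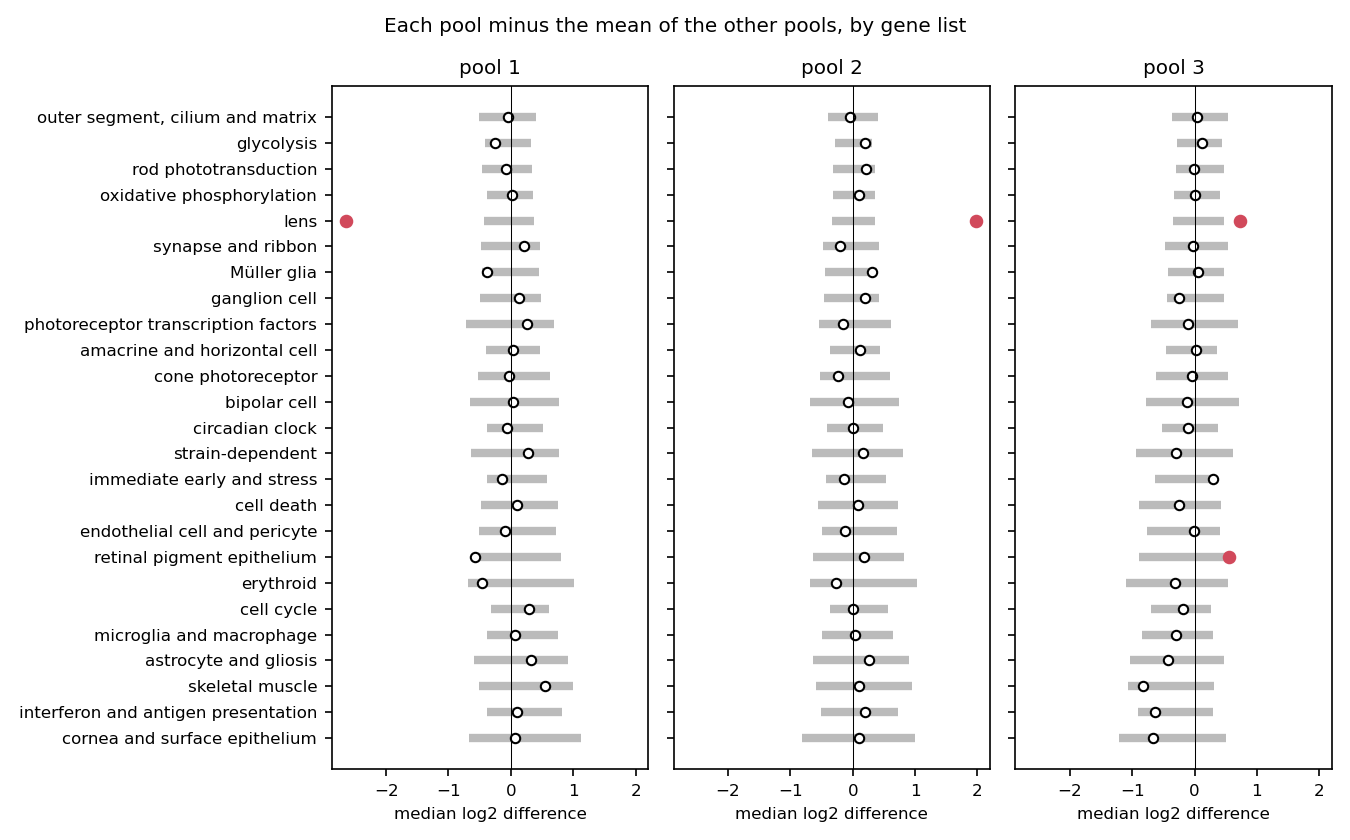
Median log2 difference of each pool from the mean of the other pools, per gene list (points), with the range of 10000 random lists of the same size matched on level, without the top and bottom 0.1% (bars). Filled points lie outside the bars: lens in all 3 pools and retinal pigment epithelium in pool 3.

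The other 23 lists stayed inside the percentiles in every pool, so that 4 of 75 list and pool pairs were outside, against 0.15 by chance for independent genes. The differences of a list in the 3 pools depend on each other, so the lens pairs form a single pattern and these counts overstate the excess. Without pool 1 and without pool 3 the count was 2, and without pool 2 it was 6. Rod phototransduction genes differed from the other pools by -0.08, 0.21 and -0.01 in pools 1, 2 and 3, and outer segment genes by -0.05, -0.05 and 0.04. Müller glial genes lay at -0.39 in pool 1 (0.33th percentile) and 0.31 in pool 2 (99.52th), and immediate early genes at 0.29 in pool 3 (99.73th). Erythroid genes were at the 30.5th percentile of level, with 3 of 7 above the floor. Their list did not shift as a whole, though the hemoglobin gene Hba-a1 had signals of 3534, 4554 and 12591 and Hbb-b2 of 830, 818 and 1612. The heme enzyme Alas2 had signals of 127, 155.5 and 309.7, and embryonic Hbb-bh1 of 286.7, 96.2 and 44.3. In simulated arrays without any change 0 of 75 pairs were called. A shift of 0.5 log2 units was recovered in 15 of 25 lists and one of 1 in all 25.

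Among single probe sets, crystallins and Xist varied between pools more than transcripts of like signal did. Of 6211 probe sets tested, 16 had a variance above that expected at their level (limma's trended prior variance, F test with Benjamini-Hochberg adjustment, threshold 0.05, n = 3), and 296 had an unadjusted p under 0.05, against 310.6 expected. The prior was fitted to the tested probe sets themselves. The closeness of the last 2 counts is therefore largely set by the fit and does not show whether an excess exists. Of these 16 probe sets, 11 belonged to the lens list, which had 16 tested; adjusted over the list alone, 14 passed. All 11 were lowest in pool 1 and highest in pool 2. Highest over lowest signal reached 25.5-fold for Crygs (limma adjusted p = 0.0072), 14.9-fold for Crygc, 18.7-fold for Crybb2 and 9.47-fold for Cryaa (adjusted p = 0.0225). It was 8.12-fold for Cryba1, 8.42-fold for Crygb, 10.6-fold for Cryab, 6.98-fold for Crygd, and 7.23-fold and 6.09-fold for the Cryge probe sets. No fold is given for Mip (adjusted p = 0.0225), which was not above the floor in pool 1. The Cryge, Crygd and Cryab probe sets carry the array's suffix for sequence families, so closely related crystallins can share their signal. A second Cryab probe set had signals of only 57.6, 147 and 45.1, and a second Crybb2 one 581, 1012 and 656.5. The remaining Cryge probe sets, with signals of 177, 253.2 and 98.7 and of 175.8, 271.4 and 280.3, did not keep the order of the called ones. Second probe sets of Crygb (324.7, 2271 and 1115) and of Crygd (50.6, below the floor, 765.4 and 412.6) did.

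The 5 probe sets outside the lens list were of Xist, Tradd, Tmem129, Cd24a and Nupr1. Xist, the RNA that coats the inactive X chromosome of females, had signals of 818, 1421 and 14.7 in pools 1, 2 and 3 (limma adjusted p = 0.0101, n = 3), the last below that array's floor of 104. Of the Y-linked genes, Eif2s3y had signals of 633.7, 265.8 and 738.5, Uty of 169.8, 53.9 and 158.8, and Kdm5d, close to or below the floor throughout, of 130.8, 123.1 and 58.3. The sex-linked list had 1 of 4 genes above the floor on all arrays and too few for a percentile. On the log2 scale the Y-linked genes were 9.01 ± 0.77, 7.04 ± 0.79 and 6.84 ± 0.55. Tradd, an adaptor of the TNF receptor, had signals of 1788, 2069 and 148.9 (adjusted p = 0.0225) in a probe set designed with fewer rules. The surface glycoprotein gene Cd24a had signals of 832, 7828 and 4182 and the stress gene Nupr1 of 197.5, 2278 and 1049, in the order of the lens genes. Tmem129 had signals of 54.4, below the floor, 1319 and 762.5 in one probe set, also designed with fewer rules, and measured 520.6, 630.0 and 937.3 in the other. Adjusted over each list alone, further calls came to 1 probe set each in the rod, outer segment, erythroid, muscle and immediate early lists, 2 in the pigment epithelium list and 1 in the sex-linked list. Only 2 probe sets were tested in each of the erythroid, muscle and sex-linked lists and 4 in the pigment epithelium list. No adjustment was made across lists, and none of these further calls passed over all tested probe sets.

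**Figure D3:**
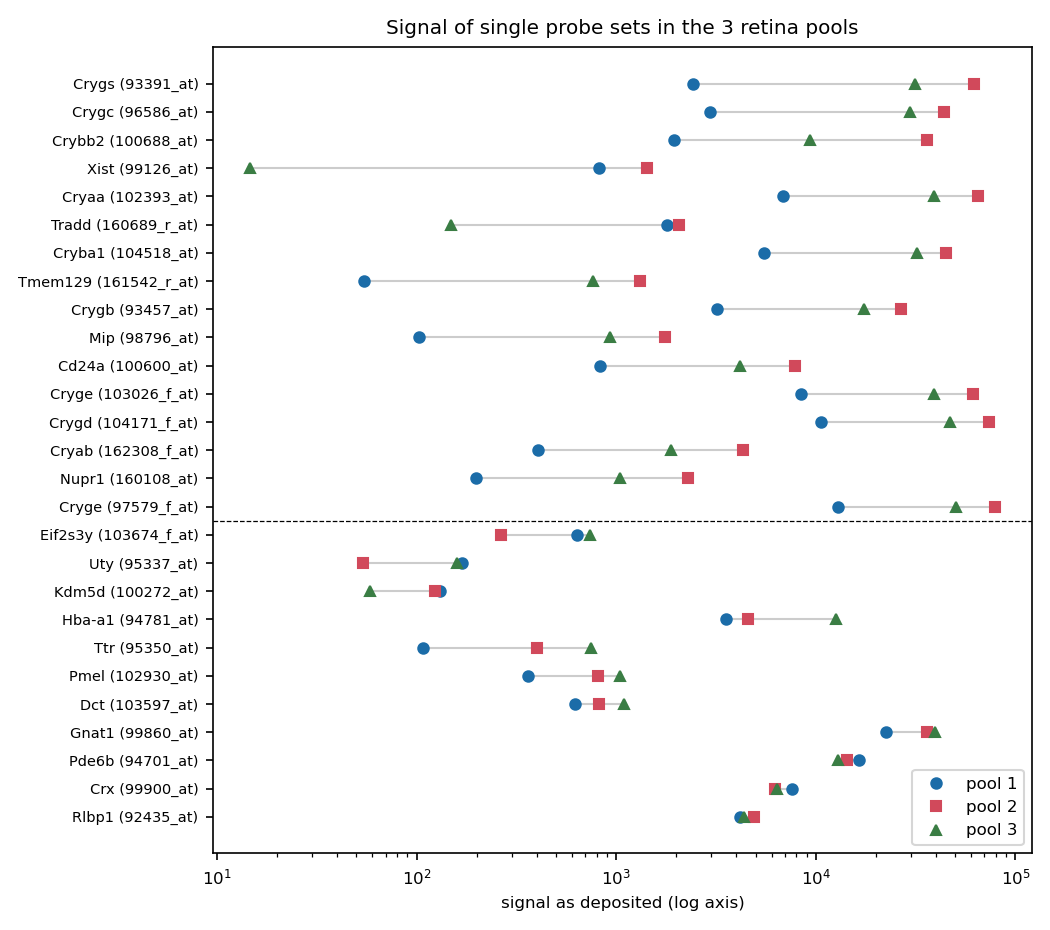
Deposited signal on a log axis for single probe sets in pools 1, 2 and 3 (symbols joined by a line). Above the dashed line are the 16 probe sets with excess variance, where Xist is at 14.7 in pool 3 and crystallins are lowest in pool 1; below it are sex-linked, erythroid, pigment epithelium, photoreceptor and Müller glial genes for comparison.

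The count of variable probe sets rests on how the expected variance was modelled and on single pools. It was 7 under quantile normalization, and 0 with an untrended prior, with a robust prior and with all dim probe sets included, where 290, 284 and 481 had an unadjusted p under 0.05. It was 2 without pool 1 (Crybb2 and Tradd), 0 without pool 2 (232 unadjusted) and 27 without pool 3, of which 14 were among the 16.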

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

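The 7 bright lists numbered 6 or 7 under the other offsets, scalings, gene summaries, limits and pool omissions, where no list was dim. Each pool alone, added after seeing the data, gave 7 in pool 1 and 6 in pools 2 and 3, and in pool 1 the interferon list was dim (percentile 0.04). Rods, outer segment, Müller glia, glycolysis, oxidative phosphorylation and lens kept their call under all of these, of which median centring cannot move a mean level, and synapse and ribbon lost it without pool 1, with the brightest probe set per gene and in pools 2 and 3 alone. The 189 list genes above the floor ranged from 163 to 200. The median spread of 0.27 became 0.273 with an offset of 0, 0.247 with an offset of 64, 0.286 with median centring, 0.370 without a filter on dim probe sets and 0.241 among the 3106 probe sets of highest signal; with 1 pool left out it was 0.210 to 0.224, where an SD of 2 values has a lower median by construction. The 16 variable probe sets became 7 under quantile normalization and 0 without the filter, without a trend in the prior and with a robust prior; leaving out a pool gave 0 to 27. The robust prior lowers the degrees of freedom of outlying probe sets by construction; for the others the cause was not tested. The same 16 passed with offsets of 0 and 64 and with median centring, which called 17. The 4 shifts became 8 with limits of 0.5% in place of 0.1%, and 2 to 6 with a pool left out, where fewer pairs exist and differences are mirror images. Raising signals under the floor to it, added after seeing the data, gave 6 and kept these 4. The lens shift of pool 3 was -0.86 without pool 1 and 2.26 without pool 2, since it is then set against a single pool; the other lens shifts kept direction and call in all alternatives. The 3′ to 5′ ratios moved by less than their SD. Dim signals limit the rest: among the probe sets of lowest signal the SD between pools was 0.63. Offsets of 0 and 64 and the brightest probe set moved 13, 32 and 27 of the 111 named genes' levels by over 1 SD, while quantile normalization moved none of them by over 1 SD and median centring cannot by construction. No paired analysis was possible because the series has a single group.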

Other observations

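Of the tests below, the 2 on the median over probe sets, the share of the pool 3 excess, the next lowest value beside Xist and the values with signals under the floor raised to it were chosen after the result was seen. The others were written down before their values were computed, when the signals of Xist, Mip and the crystallins were already known. Outside the lens list, 15 probe sets had signals in the pools much like those of lens genes, with a signal of at least 500 in pool 2, at least 4 times that of pool 1, and pool 3 at 2 times pool 1 or more; 1 of them, unnamed, was higher in pool 3 than in pool 2. Besides Cd24a, Nupr1 and Tmem129 they included Hmox1, the heme-degrading enzyme, with signals of 657, 3914.5 and 2072 in pools 1, 2 and 3, the extracellular matrix genes Fbln1 (428, 2298 and 879) and Col18a1 (100, 895 and 238), the calcium-binding S100a6 (166.8, 842 and 583.5), Emp3 (131.6, 704 and 342) and Cd151 (158.6, 791.5 and 371). Of the 15, only Cd24a, Nupr1 and Tmem129 passed the adjusted threshold, 11 did not (limma adjusted p from 0.133 for Hmox1 to 0.724) and 1 was too dim to be tested. The other 5 orders of the pools gave 1 to 10 such probe sets, so 15 is not far enough above 10 to set chance aside by the bound written beforehand. The deposited values showed no general dimming of array 1 at the level of these probe sets. Over 4941 probe sets of like mean level, pool 2 minus pool 1 had a median of -0.0017 log2 units (SD 0.53). The common scale of the deposited arrays holds such a median near 0. A dimming before that scaling cannot be judged from it. Array 1 had the fewest signals under 16 (4.49% of probe sets) but also the highest floor, so that share does not decide it. The median of 2.55 over the 15 was set by how they were chosen. It therefore cannot tell whether these single probe sets read low on array 1. Most of the 15 had pool 1 signals under the floor of 168, so their folds are not exact.

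Some photoreceptor genes had uneven signals without passing the threshold adjusted over all tested probe sets. Prph2 had signals of 1375, 1754 and 5542.5 in pools 1, 2 and 3 (adjusted p = 0.311 over all tested probe sets), Guca1a of 1752, 5118 and 5558 (adjusted p = 0.478), Opn1sw of 1593, 2073 and 4083, and Opn1mw of 775, 958 and 1776. Adjusted over each list alone, without adjustment across lists, 1 outer segment, 1 rod and 0 cone probe sets passed, and the lists as wholes stayed within the percentiles. Fabp7, a fatty acid-binding protein of immature glia, had signals of 1479, 466.5 and 370.3 (adjusted p = 0.568).

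The spread of lens transcripts between pools is a pattern that lens tissue carried along at dissection may explain. A scaling factor is argued against, since it would move all probe sets of an array alike, and pool 2 minus pool 1 had a median of -0.0164 over all probe sets and 2.96 over the lens list. The common scale of the deposited arrays holds the first value near 0, so only the gap between these medians counts. Carried lens tissue needs lens genes other than crystallins to move too. Mip did, with signals of 102.6, below the floor, 1756 and 936 in pools 1, 2 and 3, but it was known before the test and left out of it. Bfsp1 and Gja3 were higher in pool 2 than in pool 1 by a median of 2.41 log2 units, past the bound written beforehand, but that bound did not ask for signals above the floor in pool 1. Gja3 was below it there, and with signals under the floor raised to it differed by 0.05, so of these only Bfsp1, at 2.66, was measured on both sides, and the test leaves carried lens tissue open. In pool 3 the excess over pool 1 was 0.138 of that of pool 2 for Bfsp1 and 0.215 and 0.175 for the Crybb2 probe sets. Over the 15 lens probe sets reaching 500 this share had a median of 0.506 (quartiles 0.391 to 0.579). Lens tissue of the same make-up in both pools would hold that share alike for all genes, apart from saturation of the brightest ones. Whether the make-up was the same is not known, so unequal shares do not decide on carried lens tissue. Expression of crystallins by the retina itself stays open, as it was not tested.

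The loss of Xist signal in pool 3 may reflect the sex of the pooled mice, with few or no females in that pool. The Y-linked genes do not settle it. Their median difference of pool 3 from the mean of the others was 0.62 log2 units, past the bound written beforehand, but that value is Uty's own, and Uty was below the floor in pool 2. With signals under the floor raised to it the median over Eif2s3y, Uty and Kdm5d was 0. Eif2s3y alone was above the floor in all pools, at 0.82 higher in pool 3 and lowest in pool 2, and its probe set carries the suffix for sequence families. Against pool 1 alone, where Xist had a signal of 818, pool 3 was at 1.17-fold for Eif2s3y and 0.94-fold for Uty. Kdm5d was below the floor in both. The Y-linked genes thus hardly set pool 3 apart from pool 1. At the level of Xist the deposited signals of array 3 were only slightly lower in the median than those of the other arrays. Over 621 probe sets of like level, pool 3 differed from the mean of the others by a median of -0.12 log2 units (SD 0.54). Xist, at -5.16, was the lowest of them (percentile 0.0805), with the next, Maz, at -2.65. It was known for this drop beforehand, so its rank decides nothing by itself. The common scale of the deposited arrays holds the median over probe sets of like level near 0. A dimming of array 3 before that scaling cannot be judged from it. Array 3 also had the largest share of signals under 16 (9.80% of probe sets). As Xist was below the floor in pool 3, the comparison was repeated with signals under the floor raised to it, where Xist was at -2.57 and Maz again next, at -1.61. Tradd, Maz (520.4, 577.8 and 73.7) and Myrf (405.5, 592.2 and 63.3) were also low on array 3 alone, while Prph2 was high there. A loss of single probe sets on that array stays open. The labels give no sex, so the reading of few or no females in pool 3 stays a hypothesis.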
